A study of Caenorhabditis elegans with 4 samples.

How the data were processed

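The study measured DNA bound by GFP-tagged DVE-1 in L4 hermaphrodites of strain OP398. Per the labels' protocols, worms were grown at 20 °C and crosslinked with 2% formaldehyde, chromatin was sheared by sonication, and 10% of the cleared lysate was kept as input DNA. The rest was precipitated with affinity-purified antibodies against GFP. The 4 libraries fell into 2 groups from their titles, ChIP and input, with 2 replicates each. Nothing in the labels says that the replicates came from separate cultures, so p-values and overlaps describe these libraries, and the spread between them may be technical.

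Peaks were called with PeakSeq, per the source column of the deposited files, and coordinates are in WormBase WS180, per the file headers. The value of each peak is a q-value, per the file headers and attributes of the deposited lists, where it stands both as the score and as a named attribute. Start and end are 1-based and include both ends, as the GFF3 format of the file headers sets. The PeakSeq version, the aligner, the thresholds, the input used for each list and the way the combined list was made are not given in the sources used here. Whether the combined list came from pooled reads is therefore unknown. Peaks of replicates 1 and 2 were given as a list per library. The q-value depends on depth and on peak width, so it was used to rank and filter peaks within a list. Where q-values of a site in different lists stand side by side, in the text or in the plot of paired peaks, no change is read from them.

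All intervals were read as deposited, with no filter. The analysis used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, figures were drawn with matplotlib 3.10.9, and 12 of 12 overlap counts equalled those of bedtools 2.31.1. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 random placements of 1 list within chromosomes, with a one-sided p whose smallest value is 0.001. Correlations were Spearman's rho over peaks that overlapped 1 peak each way, with 100000 permutations. Shares have exact Clopper-Pearson 95% intervals. Densities were compared by an exact two-sided binomial test and by a bootstrap of 1 Mb blocks with 2000 draws. For ratios per gene, peaks per Mb were resampled by block and then rescaled by the gene counts of whole chromosomes. The length of a chromosome was the highest peak end on it in any list. Intervals and tests over peaks cover counting error only.

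Overlap and density steps were tested on simulated data. Simulated lists of 1500 peaks, drawn with 31.5%, 58.7% and 89.1% shared, gave 32.6%, 59.1% and 89.1%. Simulated X to autosome ratios of 0.5 and 1 were recovered with means of 0.508 and 1.01 over 50 runs each, and 96% and 94% of the bootstrap intervals held the true ratio. The simulated 1 Mb blocks were independent, with the same mean on every autosome, unlike the real lists. This coverage need not hold for the real lists.

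The gene table at hand is in the assembly WBcel235, not WS180, and no genome sequence was used. Positions were not converted between builds. The planned share of peaks at gene starts, the tests of 28 gene lists fixed in advance and the search for 12 motifs were therefore not run, and no gene is assigned to a site. The table served only to count protein-coding genes per chromosome, 19971 on the nuclear chromosomes. The rule for named items was fixed before the data were examined: a set of stress-response genes, the genes at the 10 strongest combined peaks, members of the gene lists, and the 3 strongest peaks of each replicate with no overlap in the other. Only its parts on peaks could be followed, and those peaks are given by position.

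The alternatives tried were a stricter overlap, a limit on the distance between midpoints, the stronger part of each list, equal list sizes, each replicate list alone, and gene number in place of length. Others were added after the data were seen: rotated lists as the chance reference, combined peaks split by the replicates that held them, lists without peaks over 4000 bp, X against chromosome I alone, and another division into centre and ends. The input libraries were not analysed here.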

Results

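Binding sites of DVE-1 were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the L4 larval stage, grown at 20 °C. DVE-1 is a homeodomain-type transcription factor known for its part in the mitochondrial unfolded protein response. The strain, OP398, carried a dve-1 transgene tagged with GFP, and chromatin was precipitated with antibodies against GFP. There were 4 libraries, 2 of ChIP DNA and 2 of input DNA, with replicates 1 and 2 in each group. The deposited peak lists covered ChIP replicate 1, ChIP replicate 2 and a combined list for the series. The input libraries were not analysed here on their own, so no background level is given. Each peak had a start, an end and a q-value from the authors' peak caller, with no read count, height or fold enrichment, and the depth of each library is therefore unknown. All coordinates are in WormBase WS180.

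The list of replicate 1 held 1550 peaks, which covered 1.21 Mb, and that of replicate 2 held 2142 peaks, which covered 1.67 Mb. The combined list held 3702 peaks over 2.96 Mb. Peaks were narrow in all 3 lists, with a median width of 560.5 bp in replicate 1, 541 bp in replicate 2 and 537 bp in the combined list. Widths in the combined list ran from 19 to 15862 bp, and 47 of its peaks were wider than 4000 bp. The q-values ran from 1.13e-100 to 0.000124 in replicate 1, from 1.49e-170 to 0.000159 in replicate 2 and from 5.30e-312 to 0.000235 in the combined list. All peaks lay on the 6 nuclear chromosomes. The number of peaks differed between the replicates, and with depth unknown this difference cannot be read as a difference in binding.

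The strongest site of the combined list lay on chromosome V from 723751 to 732021, was 8271 bp wide and had a q-value of 5.30e-312. The same region held the strongest peak of replicate 2 (q = 1.49e-170) and the peak ranked 3 in replicate 1 (q = 7.92e-88). The next site, on chromosome II from 10541811 to 10557672, was the widest peak of the combined list at 15862 bp (q = 2.88e-256). It was split into 4 peaks in replicate 1 and 2 peaks in replicate 2. Another site on chromosome V, from 6220672 to 6230061, was 9390 bp wide (q = 8.41e-227) and ranked 2 in replicate 1 and 3 in replicate 2. Chromosome I carried a site from 7656359 to 7661583 (5225 bp, q = 5.76e-181), with peaks ranked 11 and 5 in replicates 1 and 2. The strongest site on X, from 16929273 to 16932013, was 2741 bp wide (q = 3.51e-177) and ranked 4 in both replicates.

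The remaining 5 of the 10 strongest combined sites were also present in both replicates. A second site on chromosome II lay from 8741252 to 8748184 (6933 bp, q = 6.99e-174). A further site on chromosome V lay from 20157248 to 20160408 (3161 bp, q = 4.07e-170). The site on chromosome I from 15064007 to 15067643 (3637 bp, q = 3.19e-167) was the strongest peak of replicate 1 (q = 1.13e-100) and ranked 2 in replicate 2 (q = 5.34e-159). It was the last peak of the chromosome in all 3 lists. The ribosomal RNA gene array is known to lie at the right end of chromosome I, and whether this site falls in it was not determined here. The last members of the group were a site on chromosome II from 14597708 to 14606525 (8818 bp, q = 1.11e-137) and a site on chromosome I from 7078928 to 7084981 (6054 bp, q = 1.91e-135). None of the 10 lay on chromosome III or IV, where the strongest combined peaks had q-values of 2.69e-85 and 3.42e-131. The genes at these sites were not assigned, because the gene table at hand is in another assembly.

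The first comparison asked whether the replicates found the same sites. Of the 1550 peaks of replicate 1, 1378 overlapped a peak of replicate 2 by at least 1 bp (88.9%, exact 95% interval 87.2 to 90.4). In the other direction, 1348 of the 2142 peaks of replicate 2 overlapped a peak of replicate 1 (62.9%, interval 60.8 to 65.0). When 1 list was shuffled within chromosomes 1000 times, the mean shares were 3.44% and 2.46% and the highest were 4.90% and 3.45%. The one-sided p of both shares was 0.001, the smallest that 1000 shuffles can give. With 1 list per library, these intervals cover counting error over peaks only, and neighbouring peaks are not independent.

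Strong sites were shared far more often than weak ones. In replicate 1 all 388 of the strongest 388 peaks overlapped a peak of replicate 2, whereas 277 of the weakest 387 did (71.6%, interval 66.8 to 76.0). In replicate 2 the share was 98.3% among the strongest 536 peaks (interval 96.8 to 99.2) and 26.7% among the weakest 535 (interval 23.02 to 30.69). All of the 100 strongest peaks of each replicate had an overlapping peak in the other, and 82 of the 100 strongest of replicate 1 overlapped one of the 100 strongest of replicate 2.

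Shared sites also had similar positions and a similar order of strength. For the 1257 peaks paired 1 to 1 between the replicates, starts differed by a median of 43 bp and ends by 45 bp, and 74.6% of starts and 73.4% of ends lay within 100 bp of each other. Peak widths were correlated across these pairs (Spearman rho = 0.829). The q-values had a Spearman rho of 0.718 across the pairs (two-sided permutation p = 1.0e-05, the smallest that 100000 permutations can give). Both correlations are across peaks, which are not independent replicates.

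**Figure D1:**
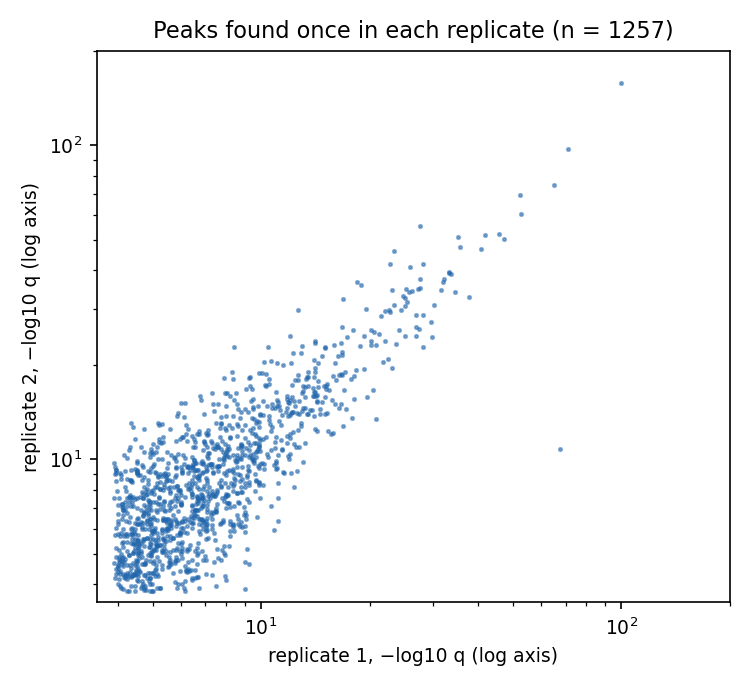
Each point is 1 of the 1257 peaks paired 1 to 1 between the replicates, with −log10 of its q-value in replicate 1 on the x axis and in replicate 2 on the y axis, both on log axes. The order of strength is similar in the replicates (Spearman rho = 0.718), and the point far to the lower right is the site on X near 438379, called over 2997 bp in replicate 1 and over 16345 bp in replicate 2.

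That site was called over very different widths. Replicate 1 had a peak on X from 438379 to 441375, 2997 bp wide, with q = 2.83e-68. The combined list had one from 438323 to 442543, 4221 bp wide, with q = 7.23e-86. In replicate 2 the site lay inside the widest peak of that list, from 425489 to 441833, 16345 bp wide, with q = 1.76e-11. The 3 q-values belong to intervals of different widths and are not compared with each other. This site was singled out after its values were seen.

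The strongest site called in only 1 replicate ranked 557 of 1550 in replicate 1 and 329 of 2142 in replicate 2. Replicate 1 had 172 such peaks, and the strongest lay on chromosome V from 11976734 to 11977154 (421 bp, q = 1.80e-08). It was followed by sites on chromosome II from 13465202 to 13465722 (q = 4.15e-08) and on chromosome IV from 2408429 to 2408882 (q = 7.56e-08). Replicate 2 had 794 such peaks, led by chromosome IV from 6575989 to 6577160 (1172 bp, q = 1.74e-13). The next were on chromosome I from 8614762 to 8615342 (q = 2.58e-12) and on chromosome III from 12849102 to 12849945 (q = 7.75e-12). All 6 sites were in the combined list. Among peaks called in only 1 replicate, 170 of 172 and 776 of 794 overlapped a combined peak. Their median q-values were 2.58e-05 in replicate 1 and 1.74e-05 in replicate 2, against 1.39e-07 and 3.87e-09 for shared peaks of the same list. A site missing from a list was not called there, which does not show that the factor was absent from it.

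The next comparison asked how much of the combined list the replicates held. Of the 3702 combined peaks, 1294 overlapped peaks of both replicates (34.95%, exact interval 33.4 to 36.5). Replicate 1 alone held 168 (4.54%), replicate 2 alone held 757 (20.4%), and 1483 overlapped no peak of either replicate (40.1%, interval 38.5 to 41.7). The peaks found in both were stronger and wider, with a median q-value of 6.25e-16 and a median width of 752 bp. Those found in neither had a median q-value of 1.74e-05 and a median width of 433 bp. Of the strongest 926 combined peaks, 879 were in both replicates (94.9%, interval 93.3 to 96.2), and of the weakest 925, 3 were (0.324%, interval 0.0669 to 0.945). The share depended on the overlap rule and on the peaks counted: it was 27.7% when at least 50% of both peaks had to overlap and 67.5% in the stronger 50% of the combined list.

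**Figure D2:**
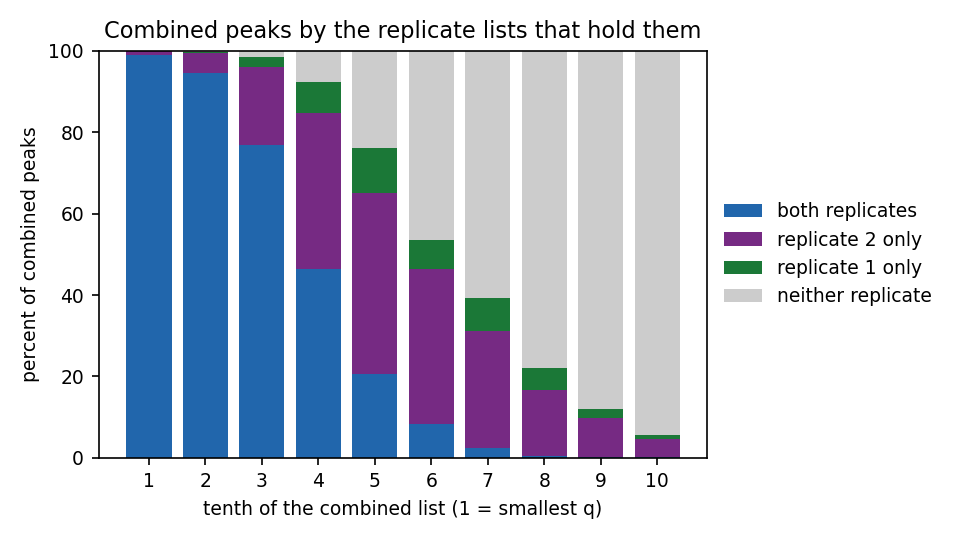
Bars give the percent of combined peaks, in 10 groups of equal size ordered from the smallest q-value (group 1) to the largest (group 10), that overlapped a peak of both replicates, of replicate 2 only, of replicate 1 only or of neither. The share in both is 98.9% in group 1, and the share in neither is 94.3% in group 10.

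The final comparison asked where on the chromosomes the sites lay. Chromosome III was the densest in the combined list, with 703 peaks or 51.1 per Mb, and X the sparsest, with 451 peaks or 25.6 per Mb. Chromosomes I, II, IV and V had 34.6, 38.6, 40.5 and 34.9 peaks per Mb. Chromosome III was also the densest and X the sparsest in both replicate lists, at 24.7 and 8.11 per Mb in replicate 1 and 32.6 and 12.2 per Mb in replicate 2. The peaks of X were wider, with a median of 672 bp in the combined list against 500 to 546 bp on the autosomes. Combined peaks covered 2.40% of the length of X, against 2.67% on chromosome I to 3.75% on chromosome III among the autosomes.

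**Figure D3:**
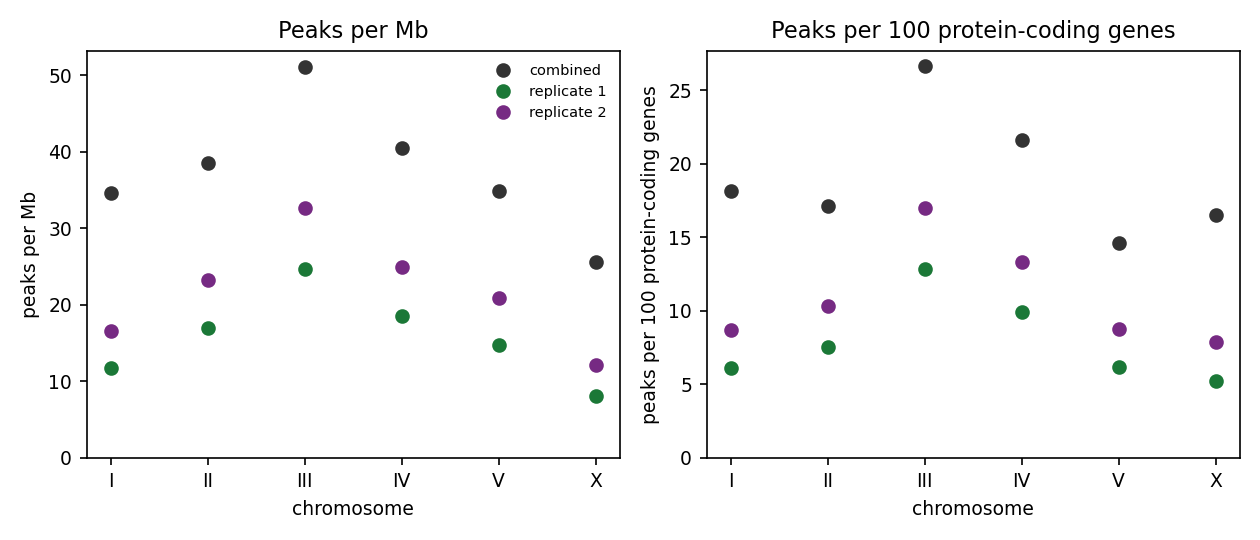
Points give peaks per Mb (left) and peaks per 100 protein-coding genes (right) for each chromosome, in the combined list and in the lists of replicates 1 and 2. Chromosome III is highest in both panels and in every list, and X is lowest per Mb but not lowest per gene in the combined list, where chromosome V has 14.61 and X 16.52 peaks per 100 genes.

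Hermaphrodites carry X in the same copy number as the autosomes. The combined list had 0.649 times as many peaks per Mb on X as on autosomes (95% block bootstrap interval 0.538 to 0.771), from 25.6 against 39.4 peaks per Mb. An exact two-sided binomial test gave p = 1.27e-19. The ratio was 0.475 in the list of replicate 1 (interval 0.380 to 0.591) and 0.522 in that of replicate 2 (interval 0.406 to 0.649). Counted per protein-coding gene, the combined list gave a ratio of 0.876 with an interval that reached past 1 (0.722 to 1.04; exact binomial p = 0.00792). Per gene, the intervals of the replicate lists lay below 1, with ratios of 0.642 in replicate 1 (0.509 to 0.795) and 0.705 in replicate 2 (0.549 to 0.882). The intervals per gene rescale a bootstrap of peaks per Mb by the gene counts of whole chromosomes. They do not cover how genes are spread along a chromosome. The binomial test treats peaks as independent, which they are not. With chromosomes as the units, 1 chromosome against 5 cannot give a permutation p below 0.167.

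Peaks were denser in the centres of chromosomes than towards their ends. The central 50% of each chromosome by length held 2277 of the 3702 combined peaks (61.5%), 1.60 times the density of the outer parts (block bootstrap interval 1.40 to 1.82; exact two-sided binomial p = 7.81e-45). The ratio was 1.76 in replicate 1 (interval 1.45 to 2.13) and 1.64 in replicate 2 (interval 1.38 to 1.94). These densities are per length only. Genes were not counted within chromosomes, so gene density and the input were not taken into account. The centre held 62.6% of autosomal combined peaks and 53.9% of those on X, a difference past Fisher's exact test (two-sided p = 0.000440). The same comparison gave 64.6% against 55.2% in replicate 1 (Fisher's exact p = 0.0286) and 63.2% against 53.5% in replicate 2 (Fisher's exact p = 0.00608). Fisher's test treats peaks as independent, which they are not, and no block bootstrap interval is given for this difference. These p-values do not cover the spread between chromosomes. Among the autosomes the combined share ran from 57.9% on chromosome III (exact interval 54.1 to 61.6) to 66.2% on chromosome V. The interval of chromosome III overlapped that of X (49.2 to 58.6), and these chromosomes were not tested against each other. The ends of each chromosome were taken from the outermost peaks, so the lengths are slightly short.

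**Figure D4:**
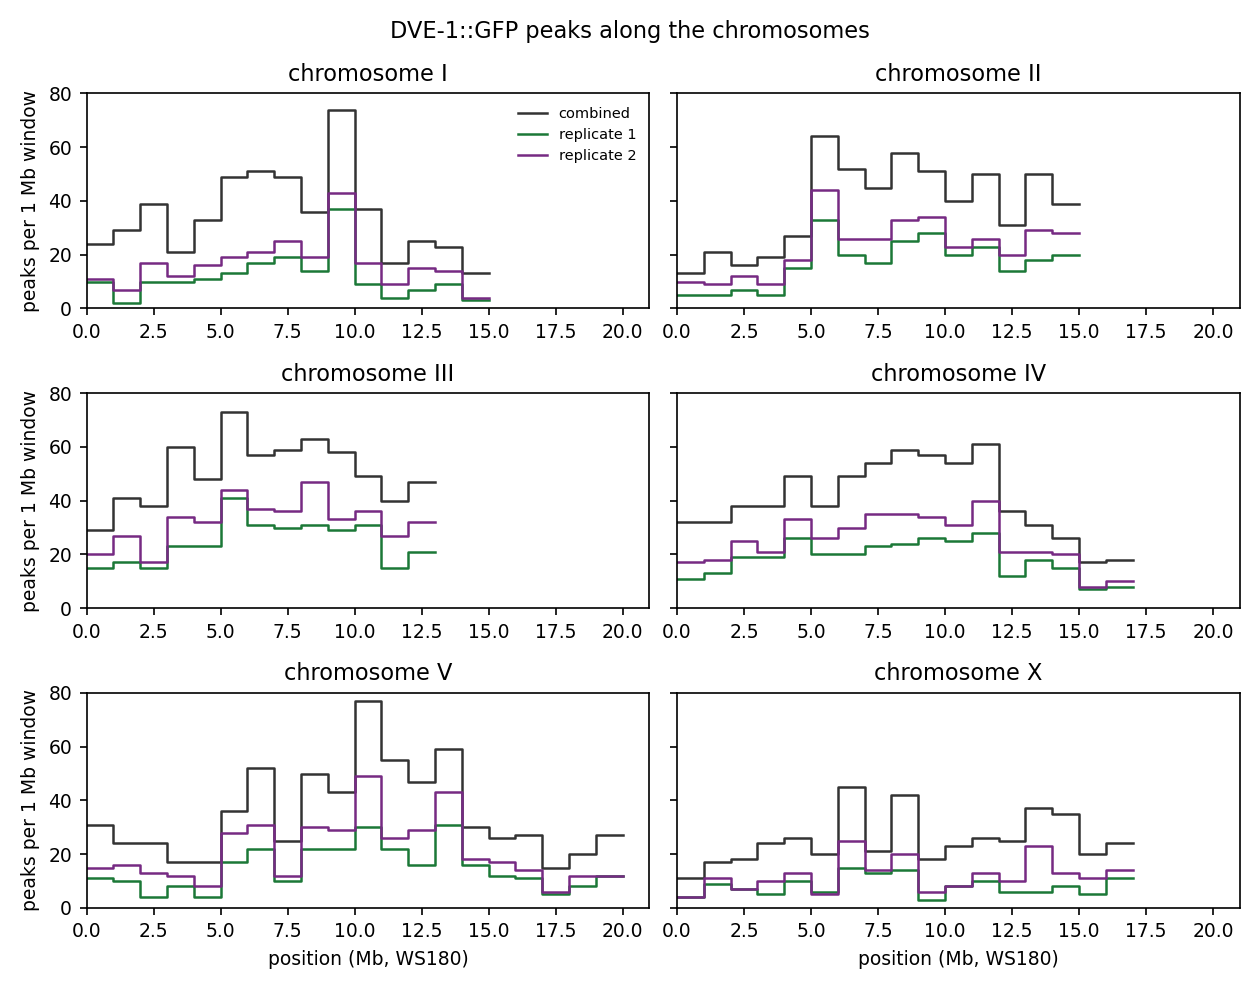
Lines give the number of peaks in each full 1 Mb window along the 6 chromosomes, with position in Mb in WS180 on the x axis, for the combined list and replicates 1 and 2. The highest window of the combined list, on chromosome V from 10000001 to 11000000, holds 77 peaks, and the lowest, on X from 1 to 1000000, holds 11.

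The share of combined peaks held by neither replicate also differed between chromosomes. It was 48.9% on chromosome I (exact interval 44.6 to 53.3) and 49.0% on X (interval 44.3 to 53.7). On chromosomes II, III, IV and V it was 37.4%, 34.1%, 36.9% and 39.2%. Chromosomes I and X together held 32.1% of the peaks found in neither replicate and 20.3% of those found in both (odds ratio 1.85, Fisher's exact two-sided p = 2.01e-12). This grouping of chromosomes was chosen after the values were seen, and Fisher's test treats peaks as independent, which they are not.

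**Figure D5:**
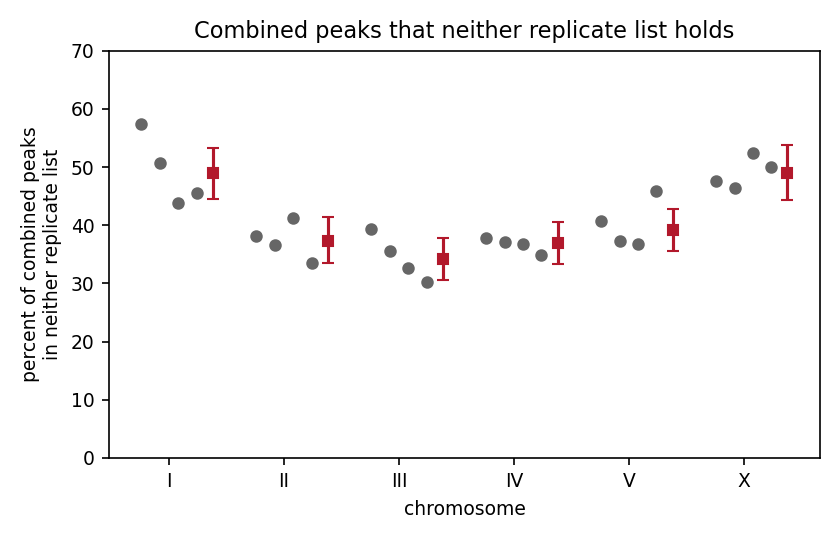
Squares give, for each chromosome, the percent of combined peaks that overlapped no peak of either replicate, with exact 95% binomial intervals, and grey points give the same percent in 4 stretches of equal length along it, from left to right. All 8 stretches of chromosomes I and X lie between 43.8% and 57.4%, and the 16 stretches of the other chromosomes between 30.18% and 45.97%.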

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

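The rotated chance reference, the subsets by replicate support or width, X against chromosome I and the other division into centre and ends were chosen after seeing the data; the rest were fixed before the data were examined. Of 28 alternative values, 26 had a test and kept the direction and the side of the threshold, whatever the change in size. The rotated lists changed only the chance reference, so the shares set against them repeat the main values. The exceptions had no test or threshold and concern the share of combined peaks found in both replicates, 34.95%. It was 27.7% when at least 50% of both peaks had to overlap and 67.5% in the stronger 50% of the combined list. The fall to 27.7% follows from construction, because every peak that meets the 50% rule also meets the rule of 1 bp. The rise to 67.5% reflects the result that strong peaks were shared more often. The share of replicate 1 peaks found in replicate 2 ran from 72.0% to 89.2% and the reverse share from 52.1% to 76.5%, all with an empirical permutation p of 0.001, the smallest possible, against placed or rotated lists. The rho of q-values was 0.710 to 0.747. The X to autosome ratio was 0.475 and 0.522 in the single replicate lists and 0.461 to 0.876 over all alternatives, below 1 with an exact binomial p under 0.05 in each, but the block bootstrap interval per gene in the combined list reached 1.04. The density ratio of centre to ends was 1.59 to 1.76. No paired analysis was possible because the groups that share replicate numbers are ChIP and input, and no list of the input libraries was analysed here. Peaks at gene starts, gene lists and motifs, with all their alternatives, were not run, for want of an annotation in WS180. The depth of the libraries is unknown, so a peak missing from a list can be below detection, and the different numbers of peaks in the replicates cannot be read as biology.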

Other observations

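The tests of clustering and of each explanation in this part were chosen after the result was seen, except the test of whether strong combined peaks in neither replicate lay on chromosomes I and X. No biological difference between samples was tested, since the design has 1 strain, stage and tag; gene number, a property of the genome, was tested for X. Sites lay close to each other more often than random placement gives. In the combined list 547 of 3696 neighbouring pairs on the same chromosome were less than 1000 bp apart (14.8%, against a mean of 6.64% and a highest value of 7.90% in 1000 shuffles within chromosomes). The shares were 11.2% against 2.97% in replicate 1 and 12.2% against 3.98% in replicate 2. The one-sided p was 0.001 in all 3 lists, the smallest the shuffles can give. The shuffles ignored the differences in peak density along a chromosome. Those differences also bring neighbours closer, so the test does not separate them from local clustering. The caller can split a broad region into neighbours, and 80 combined peaks covered more than 1 peak of replicate 1 and 84 more than 1 peak of replicate 2.

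The densest full 1 Mb windows of the combined list were on chromosome V from 10000001 to 11000000 (77 peaks), on chromosome I from 9000001 to 10000000 (74) and on chromosome III from 5000001 to 6000000 (73), against a median of 36 over 97 windows. The window on chromosome III was the densest of replicate 1 (41 peaks), and the window on chromosome V was the densest of replicate 2 (49). The first Mb of X held 11 combined peaks, the fewest of any full window. Peaks over these windows varied more than a constant rate gives, with a variance 6.78 times the mean in the combined list.

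More combined peaks were in neither replicate on chromosomes I and X (49.0%) than on II to V (36.9%), a difference of 12.1 points (block bootstrap interval 8.22 to 16.17). Within 5 groups of similar combined q-value the difference was 8.31 points (5.41 to 11.2), so strength between these groups did not account for all of it. Peak strength as the whole cause stays open, because the share in neither also changed steeply inside such a group. It was 23.8% and 46.5% in groups 5 and 6 of 10 by q-value, which make up about 1 of these 5 groups. The choice of I and X for their high shares also favours a difference above 0. A step in the making of the lists that acted per chromosome stays open: 8 of 8 stretches of I and X lay above the median of those of the other chromosomes, 37.0%, but these chromosomes were grouped for their high shares, so this largely restates the choice. The last stretch of V, at 45.97%, also lay above 2 stretches of chromosome I. Both tests were first run on the ratio of a peak's −log10 q in a replicate list to that in the combined list. They were moved to overlap after that result was seen, because q-values of different lists are not comparable.

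X had fewer peaks per Mb than the autosomes. Gene number alone stays open. Peaks per gene on X were 0.642 and 0.705 times the autosomes in the replicate lists, with intervals below 1, and 0.876 times in the combined list. Those intervals do not cover the spread between chromosomes, and the autosomes also differed per gene. In replicate 1, X had 5.24 peaks per 100 genes, against 6.12 on chromosome I to 12.87 on chromosome III. In replicate 2, X had 7.88, against 8.69 on chromosome I to 16.99 on chromosome III. X was lowest in both lists, but 1 chromosome against 5 cannot decide. A step on I and X alone stays open: X had 0.740 times the density of chromosome I in the combined list (interval 0.567 to 0.989), 0.694 in replicate 1 (0.469 to 1.06) and 0.735 in replicate 2 (0.533 to 1.05), and exact binomial tests, which treat peaks as independent, gave p = 2.96e-06, 0.00133 and 0.000944 against equal densities. For gene number and a step together, X against I per gene gave 0.912, 0.856 and 0.906 in the combined list and replicates 1 and 2, with intervals that included 1. This stays open too, because chromosome I had the fewest peaks per gene of the autosomes in both replicate lists (6.12 and 8.69 per 100 genes) but close to those of V (6.15 and 8.75), which lacked the excess, and in the combined list I had 1.24 times as many per gene as V (interval 0.918 to 1.65, exact binomial p = 0.000214).

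Of 1211 combined peaks with q under 1e-10, 13 were in neither replicate, led by chromosome IV from 13250196 to 13252821 (2626 bp, q = 4.21e-19). A step on chromosomes I and X stays open, since 6 of the 13 lay there (46.2%, exact interval 19.2 to 74.9) against 23.5% of all such strong peaks. Among these 6, only the peak from 3968456 to 3970571 lay on X, and the others lay on chromosome I. Broad regions of low signal, called only with more reads, could also be the source and stay open: the median width of the 13 was 1.68 times that of the peaks found in both replicates, 1366 against 814 bp (two-sided permutation p = 5.7e-02). The 13 peaks are too few to decide.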
